A study of Mus musculus with 39 samples.

How the data were processed

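Liver and triceps surae muscle of 25-week-old female Ins1-/- mice, either Ins2+/- or Ins2+/+ and fed diet A or diet B, were profiled by RNA sequencing. Per the labels' protocols, 400 ng of RNA per sample was made into libraries with the TruSeq RNA kit version 2, and the libraries were sequenced on a HiSeq 2500 over 2 rapid-run lanes. The labels do not say which library ran on which lane, so no lane term could be fitted. This kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes, bcl2fastq 1.8.4, kallisto 0.42.3, the mouse build GRCm38 and DESeq2 (version not given) were used, with no role stated for DESeq2. The deposited tables hold kallisto's estimated counts per gene, 46517 genes in each, with no further normalization found in the values. Kallisto divides reads among transcripts by likelihood, so values of near-identical genes depend on that division and are treated as uncertain. Only 53 of 3302 long intergenic noncoding RNA genes had any count, and Xist had none in any library, so noncoding genes are barely covered.

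Estimated counts were rounded to whole numbers. Gene symbols and coordinates came from the GENCODE mouse release 21 annotation of GRCm38, matched by gene identifier without its version. It covered 46005 of the 46517 identifiers (98.9%); the 512 others held 0.264% of all counts and kept their identifiers, and 118 identifiers share a symbol with another. Groups came from the sample labels, and liver Ins2+/+ on diet B has replicates 2 to 5. Pairs of libraries within a group were compared by a chi-square test on counts thinned binomially to 2400000 per library, and to 1000000 to include the 3 libraries with fewer. Livers Ins2+/- B 2 and B 3 had a chi-square per degree of freedom of 1.31 and 1.12, and the next pair 4.01 and 2.52. At full depth their value was 6.33, also the lowest of all pairs, and Scd1 stood at 2857 and 1969 CPM. They were kept as 2 libraries and taken as 1 in an alternative. Their counts differed beyond sampling noise, which does not show that they come from 2 animals. If they come from 1 animal, p values of liver comparisons are too small.

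Within each tissue, edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, filterByExpr by group, estimateDisp and the quasi-likelihood test (glmQLFit without robust estimation, glmQLFTest). The 4 groups of a tissue shared one estimate of the spread, with 15 residual degrees of freedom and 11777 genes in liver and 16 and 11959 in muscle. Contrasts were genotype averaged over diets, genotype on each diet, diet averaged over genotypes, and the interaction. Liver and muscle effects were compared in a fit over all 39 libraries and 10517 genes, with 31 residual degrees of freedom. P values were adjusted by Benjamini and Hochberg's method over all genes tested, and a gene was called at an adjusted p below 0.05. The SE of a log2 ratio is its size divided by the square root of F. For genes that vary less than counting noise edgeR raises p, so SE and p can then differ. The number of libraries showing a direction counts the libraries of the shifted group that lie on that side of the mean of the other group within the same diet or genotype.

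Gene lists for insulin action, metabolism, stress, muscle and linkage to Ins2 (25) and markers of cell types in or near the tissues (12) were fixed beforehand. A list was tested with at least 5 tested members, which left 32 lists in liver and between tissues and 37 in muscle. Camera (limma 3.58.1) compared each list with the other genes at a preset correlation of 0.01, and again with a correlation estimated per list. The self-contained test fry asked whether a list moves one way on balance. Members were also adjusted over the list alone. The comparison of genes near Ins2 used a window of 10 Mb and Fisher's exact test. Named genes were fixed by rule: Ins1 and Ins2; 13 liver and 10 muscle genes of insulin action; the 8 called genes of lowest adjusted p per direction, without symbols of Gm and digits or ending in Rik; where none was called, the 3 genes of lowest p per direction; and up to 4 called members per list. The remaining 10 called liver diet genes, and the 3 members of lowest p in each list that camera called, were chosen after the results were seen. Some genes that meet the rule are not reported here.

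The design, tests, lists, naming rule and the following alternatives were chosen before the data were examined: DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a stricter filter (1 CPM in 4 libraries and a mean count of 20), the replicate number as a block, the first surrogate variable (sva 3.50.0), limma-voom with sample weights, an adjusted p below 0.1, only the groups compared, other windows around Ins2, and each library left out in turn. Fits with robust estimation, without or adjusted for islet transcripts (5 CPM or more; log2 of CPM plus 0.1), without 4 muscles that stood apart, without the replicate 1 livers, without the 2 deepest livers, and with these 2 livers as 1 library of their mean counts were added after seeing the data. No rule was set for picking the 4 muscles. On the first principal components Ins2+/+ B 4 (27.4 and 29.6) lay nearer most muscles than Ins2+/- A 2 (−37.2 and −6.9), which was kept. Robust and other fits had been looked at during exploration, and the non-robust fit was kept as first written. Exact permutation and Fisher's tests used scipy 1.17.1.

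The tests were tried on simulated counts drawn from the real means, depths and spreads with 200 genes changed. edgeR's false share among calls was 5.17% to 8.82% over the comparisons simulated, and DESeq2's 7.45% to 29.3%. For liver diet (11642 genes run) edgeR recovered 72.6%, 86.4% and 98.5% of genes changed 1.5-, 2- and 4-fold, and for muscle diet (11611 genes run) 7.35%, 54.3% and 79.6%. For the liver interaction (11648 genes run) it recovered 17.2%, 52.6% and 90.8%, and for the muscle interaction (11631 genes run) 0%, 6.56% and 40.3%. One list, the neighbours of Ins2, was moved 1.5-fold in 4 comparisons and recovered in each, with 0 of 25 to 30 unchanged lists called. The simulated genes were drawn independently of each other, from spreads that edgeR itself had fitted, so these 0 false lists do not carry over to the real libraries. For the same reasons the false shares and the recovered shares need not hold there, nor rank edgeR against DESeq2. Random splits of the real libraries gave up to 19 called lists, and up to 101 genes called by edgeR in muscle.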

Results

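Gene expression was measured by RNA sequencing in liver and in triceps surae, the muscle group of the calf, from female mice aged 25 weeks. All mice lacked Ins1, one of the pair of mouse insulin genes, and carried either both working copies of the other gene (Ins2+/+) or a single one (Ins2+/-). The design therefore asked what a lower insulin gene dose does to the transcriptome of organs that respond to insulin, and whether diet alters that effect. Mice of each genotype ate diet A, a chow of moderate energy content (4.68 kcal per g), or diet B, which was richer in energy (5.56 kcal per g). Fat supplied 25% of the calories of diet A and 58% of those of diet B, and carbohydrate 55% and 26%. Tissue was taken after a fast of 4 h. Each group held 5 libraries, except Ins2+/+ livers on diet B with 4, which gave 19 liver and 20 muscle libraries. The labels describe the replicates as mice of the same litters, so each library is treated as an animal. Libraries are named by group and replicate number, so that liver Ins2+/- B 1 is the first Ins2+/- liver on diet B. Livers Ins2+/- B 2 and B 3, the 2 deepest, were far more alike than any other pair of a group (chi-square per degree of freedom of 1.31 at 2400000 counts each, against 4.01 or more). They differed beyond counting noise at full depth (6.33), and in Ins2 (0.295 and 26.2 CPM), and were kept as 2 libraries. Neither difference shows that they come from 2 animals, since 2 libraries of 1 animal could also differ so. Whether they come from 1 animal is not known, in which case n = 5 is too high for that group.

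The total of estimated counts per library ran from 1289225 to 54249818 in liver (median 4847998) and from 1060469 to 13709576 in muscle. A count of 0 allows up to 3 counts, which was 0.0553 to 2.33 CPM (counts per 1e+06 counts of the library) in the livers and 0.219 to 2.83 CPM in the muscles. These floors cover counting error alone, because reads copied by PCR without molecular identifiers are not independent molecules. Libraries of one group differed by a biological coefficient of variation, as edgeR terms it, of 19.1% in liver and 51.8% in muscle. Muscle comparisons were thus the less precise. These values hold differences in library content and quality as well as those between animals. In simulated counts for the averaged genotype comparison, 84.1% of genes given a 2-fold change were recovered in liver (11634 genes run) and 36.4% in muscle (11666 genes run). One muscle library, Ins2+/- B 2, held 49.71% of its counts on mitochondrially encoded genes, against 13.74% to 26.8% in the other muscles. Below, levels are normalised CPM as mean ± SD with n = 5 per group (n = 4 for Ins2+/+ livers on diet B), and differences are log2 ratios ± SE. Every adjusted p without another name is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and gene lists were compared with the other genes by camera.

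The targeted genes came first. Ins1 had 0 counts in all 19 livers and in 18 of 20 muscles, and the other two muscles, Ins2+/- A 2 and Ins2+/- B 5, held 3 and 11 counts. Ins2, whose hormone is normally made in pancreatic beta cells, was nevertheless read in both tissues, at 0.199 to 2070 CPM in liver (median 0.776) and 0.465 to 12900 CPM in muscle (median 7.17). Its mean in liver was 4.42 ± 8.28 CPM in Ins2+/+ and 56.2 ± 77.4 CPM in Ins2+/- mice on diet A, and 19.7 ± 38.5 and 406 ± 894 CPM on diet B. The muscle means were 264 ± 570 and 725 ± 1610 CPM on diet A, and 540 ± 947 and 3898 ± 5527 CPM on diet B. The estimates for Ins2+/- against Ins2+/+ averaged over diets, 3.96 ± 1.45 in liver (adjusted p = 0.412) and 2.16 ± 1.55 in muscle (adjusted p = 0.999), did not pass. Ins2 therefore checks no Ins2 label here, while the near absence of Ins1 beside 124823 Ins2 counts in the 15 libraries that also held other islet hormones goes with the Ins1-/- labels.

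Ins2 came with the other islet hormones. The transcripts of Iapp, Gcg, Sst and Ppy, which encode amylin, glucagon, somatostatin and pancreatic polypeptide, reached 5 CPM together in 6 of 19 livers and 9 of 20 muscles. This threshold was set after these levels had been seen. Among those 6 livers their log levels rose with Ins2 (Pearson r = 0.994, exact permutation p = 0.0014, adjusted 0.0019; Spearman rho = 1, exact permutation p = 0.0028). Among the 9 muscles r was 0.993 (exact permutation p = 8.3e-06, adjusted 3.3e-05) and rho 0.983 (exact permutation p = 5e-05). Without the 2 libraries farthest from the median, r was 0.977 in liver and 0.979 in muscle. Ins2 was also compared with the sum of acinar markers. In the 9 muscles r was 0.905 (exact permutation p = 0.00039, adjusted 0.00078) and rho 0.9 (exact permutation p = 0.002), and in the 6 livers r was 0.774 (exact permutation p = 0.053, adjusted 0.053) and rho 0.943 (exact permutation p = 0.017). These were the 4 relations tested. Islet transcripts were found in every group. By Fisher's exact test, two-sided, the share of such libraries was not shown to differ between genotypes (4 of 10 Ins2+/- against 2 of 9 Ins2+/+ livers, p = 0.628, adjusted 1; 5 of 10 against 4 of 10 muscles, p = 1) or diets (p = 1 in each tissue).

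**Figure D1:**
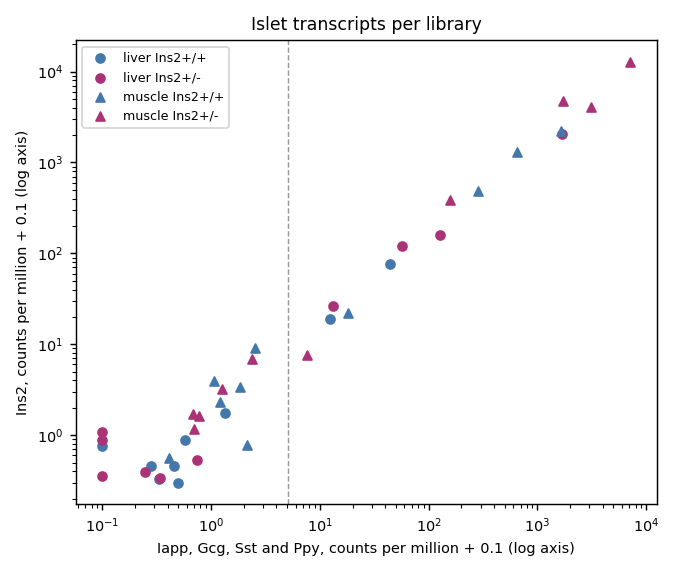
Each point is a library, with the sum of Iapp, Gcg, Sst and Ppy on the x axis and Ins2 on the y axis, both in CPM plus 0.1 on log axes, and the dashed vertical line marks a sum of 5 CPM. The 6 livers and 9 muscles to its right climb along a common diagonal, up to the muscle library Ins2+/- B 4 with 12900 CPM of Ins2.

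Few single liver genes were called between the genotypes by edgeR's test. Of 100 random splits of the livers, the real one included, 7 called as many genes averaged over the diets, so chance stays open. Averaged over the diets, 1 of 11777 tested genes differed between genotypes. Grpel2, which encodes a nucleotide-exchange factor of the mitochondrial Hsp70 chaperone (ENSMUSG00000024580, GRCm38 chromosome 18, 61712424 to 61726325, minus strand), fell by 0.43 ± 0.06 in Ins2+/- livers (0.742-fold, adjusted p = 0.0053). All 10 Ins2+/- livers lay below the Ins2+/+ mean of their diet. Levels were 69.3 ± 5.93 and 47.2 ± 1.78 CPM in Ins2+/+ and Ins2+/- livers on diet A, and 85.6 ± 7.99 and 68.6 ± 5.23 CPM on diet B. At an unadjusted p under 0.05 there were 1136 genes, where 589 are expected by chance. In muscle, where it was examined only after the liver result was seen, Grpel2 had an estimate of −0.65 ± 0.26 (adjusted p = 0.999).

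None of the liver genes fixed beforehand for insulin action passed. The lowest estimates were those of Scd1, the stearoyl-CoA desaturase of fat synthesis, at −1.23 ± 0.41 (adjusted p = 0.38; lower in 9 of 10 Ins2+/- livers) and Irs2, an adaptor of the insulin receptor, at −0.76 ± 0.27 (adjusted p = 0.39; lower in 10 of 10). Scd1 stood at 7980 ± 7490 and 2710 ± 1600 CPM in Ins2+/+ and Ins2+/- livers on diet A and at 5820 ± 2310 and 3090 ± 2310 CPM on diet B. One Ins2+/+ liver on diet A, A 3, carried 21000 CPM of it. Without that liver the estimate was −0.86. The counts of livers compare with the Ins2+/+ mean of the same diet, and single livers of the genotypes overlapped for both genes. Irs2 ranged from 4.401 to 27.79 CPM in Ins2+/+ and from 4.814 to 9.484 CPM in Ins2+/- livers on diet A. On diet B its ranges were 14.15 to 33.12 and 13.39 to 18.88 CPM. The insulin receptor gene Insr (−0.05 ± 0.09), the growth factor gene Igf1 (0.03 ± 0.11), the gluconeogenic genes Pck1 (0.26 ± 0.19) and G6pc (0.07 ± 0.20), and Srebf1 (−0.15 ± 0.13) and Fasn (−0.15 ± 0.22) of lipogenesis lay near 0. So did Irs1 (−0.30 ± 0.20), Igfbp1 (−0.09 ± 0.38), Igfbp2 (0.27 ± 0.13) and Ppargc1a (−0.03 ± 0.15).

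Several gene lists passed camera's test, none of them with an estimated correlation. Of 24 genes of glycolysis and lipogenesis, 23 had lower estimates in Ins2+/- livers, among them Scd1, Acacb (−0.78 ± 0.27) and Acss2 (−0.76 ± 0.28), which make malonyl-CoA and acetyl-CoA (camera adjusted p = 0.000278). Without liver Ins2+/+ A 3 Acacb was at −0.47 and Acss2 at −0.33. Cholesterol synthesis was also lower (19 of 24 genes, camera adjusted p = 0.00358), with Sc5d at −0.40 ± 0.11, as were markers of stellate cells and fibroblasts (7 of 7, camera adjusted p = 0.0131), with Lrat at −0.39 ± 0.12. Adjusted p was 0.434, 0.647 and 0.24 for these 3 lists with an estimated correlation. Higher in Ins2+/- livers were all 14 markers of Kupffer cells, the resident macrophages (median 0.287, camera adjusted p = 3.11e-08), with Marco at 1.26 ± 0.43 and C1qc at 0.40 ± 0.12, and 34 of 36 ribosomal protein genes (camera adjusted p = 3.11e-08), with Rplp0 at 0.36 ± 0.11. Interferon-response genes followed (22 of 24, camera adjusted p = 0.000278), with Irf7 at 0.43 ± 0.15. Adjusted p was 0.243, 0.434 and 0.434 for these with an estimated correlation. Also higher were 6 of 6 erythroid genes (camera adjusted p = 0.000214), 8 of 10 hepatocyte markers (0.0138) and 19 of 27 genes of the unfolded protein response (0.0272). For those 3, adjusted p was 0.344, 0.434 and 0.596 with an estimated correlation. Of 100 random splits of the livers, the real one included, 37 gave as low a p for cholesterol synthesis. The count was 23 for interferon and for unfolded-protein genes, 19 for glycolysis and lipogenesis, and 10 for hepatocyte markers. It was 7 for erythroid genes, 5 for stellate markers, and 4 for Kupffer markers and for ribosomal proteins.

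Markers of pancreatic acinar cells moved with the same contrast. All 11 had higher estimates in Ins2+/- livers (median 3.61, camera adjusted p = 0.000689, adjusted p = 0.585 with an estimated correlation), but Cela2a (4.22 ± 1.35), a pancreatic elastase, was higher in only 4 of 10 livers. Adjusted over the list alone, 11 acinar genes, 1 cholesterol gene (Sc5d, lower) and 1 stellate marker (Lrat, lower) passed, and no member of the other 8 lists did. Of the 32 lists, 21 did not pass. The Grpel2 call ended without the 6 livers that held islet transcripts (−0.45, adjusted p = 0.12), and DESeq2 called 32 genes and limma-voom 14 where edgeR called 1.

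On diet A alone, Grpel2 was again the single call, which fell by 0.55 ± 0.08 (adjusted p = 0.025; 5 of 5 Ins2+/- livers), among 1195 genes at an unadjusted p under 0.05. Its estimate on diet B was −0.31 ± 0.09 (adjusted p = 0.864), and the difference between the diets was 0.23 ± 0.12 (adjusted p = 0.981). Irs2 stood at −1.21 ± 0.40 and Scd1 at −1.56 ± 0.58, each below the Ins2+/+ mean in 5 of 5 Ins2+/- livers (adjusted p = 0.32 and 0.36). Single livers overlapped. Liver Ins2+/+ A 4 had 4.401 CPM of Irs2, below every Ins2+/- liver on this diet. Its Scd1, at 2140 CPM, was above that of Ins2+/- A 2 (501.4 CPM) only. Irs2 was at −0.77 without liver Ins2+/+ A 2 and Scd1 at −0.80 without Ins2+/+ A 3. The other fixed genes ranged from −0.59 ± 0.28 (Irs1, −0.39 without liver Ins2+/- A 1) to 0.48 ± 0.19 (Igfbp2). Of the interferon-response genes 23 of 24 were higher (median 0.415, camera adjusted p = 1.11e-07), with Irf7 at 0.71 ± 0.21 and the antiviral membrane protein gene Bst2 at 0.24 ± 0.09. All 14 Kupffer markers were higher too (camera adjusted p = 4.89e-07), with C1qc at 0.64 ± 0.17. Adjusted p was 0.373 for each of these with an estimated correlation. Insulin-signalling genes were lower as a group (19 of 30, camera adjusted p = 0.0172, adjusted p = 0.0909 with an estimated correlation), with 5 lower when adjusted over the list alone. Members with lower estimates included Tsc1 (−0.61 ± 0.18), a brake on mTORC1, and the kinase gene Pik3cb (−0.52 ± 0.15), each lower in 5 of 5 livers. By fry, which tests whether a list moves one way on balance, this list and that of Ins2 neighbours passed (adjusted p = 0.0179 each).

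Other lists passed camera's test on diet A. Genes of the circadian clock (14 of 17 lower, camera adjusted p = 0.0413), of glycolysis and lipogenesis (22 of 24 lower, 0.0172) and of glucose use in muscle (16 of 21 lower, 0.0413) had adjusted p of 0.571, 0.697 and 0.387 with an estimated correlation. Their members included the clock repressor gene Cry2 (−0.55 ± 0.20), malic enzyme Me1 (−0.81 ± 0.28, and −0.43 without liver Ins2+/+ A 3) and the AMP-kinase subunit gene Prkaa2 (−0.35 ± 0.12). Ribosomal protein genes (31 of 36 higher, camera adjusted p = 2.13e-06), hepatocyte markers (8 of 10, 0.00559) and extracellular matrix genes (15 of 20, 0.0436) had adjusted p of 0.571, 0.4 and 0.62 with an estimated correlation. Adjusted over the list alone, 1 Kupffer and 1 hepatocyte marker were higher. Of 100 random splits, 47 gave as low a p for glycolysis and lipogenesis, 29 for matrix and 23 for clock genes. The count was 22 for ribosomal proteins, 13 for hepatocyte markers, 10 for glucose use, 9 for interferon genes, 6 for Kupffer markers and 4 for insulin signalling. Of the 32 lists, 22 did not pass. The Grpel2 call on diet A was lost in several other fits, among them that with the replicate number as a block. DESeq2 called 14 genes, and without liver Ins2+/+ A 1 the count was 8.

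On diet B edgeR called 0 genes between genotypes, with 500 at an unadjusted p under 0.05; DESeq2 also called 0 and limma-voom 37. The genes with the lowest p in each direction were Xlr3a (2.40 ± 0.57), Fbxo33 (0.60 ± 0.16) and Pcp4l1 (0.61 ± 0.16), and Jun (−2.34 ± 0.52), Gdf15 (−2.31 ± 0.51) and Jund (−0.79 ± 0.16), with adjusted p from 0.52 to 0.86 and all 5 Ins2+/- livers on the stated side. Gdf15, a stress-induced hormone, averaged 24.3 ± 20.4 CPM in Ins2+/+ and 5.37 ± 2.07 CPM in Ins2+/- livers on this diet. Estimates of the fixed genes ranged from −0.91 ± 0.60 (Scd1) to 0.48 ± 0.29 (G6pc), and none passed. All 24 cholesterol-synthesis genes were lower in Ins2+/- livers (median −0.278, camera adjusted p = 2.72e-11, adjusted p = 0.281 with an estimated correlation), with 2 lower when adjusted over the list alone. Dhcr7 (−0.57 ± 0.16) and Sc5d (−0.53 ± 0.16) of the last steps of the pathway and the sterol sensor gene Insig1 (−0.54 ± 0.18) were lower in 5 of 5. Immediate early genes respond within minutes to growth and stress signals, and their list also holds heat shock genes. Of its 16 tested members 10 were lower (camera adjusted p = 0.000302, adjusted p = 0.281 with an estimated correlation), with Fos at −3.74 ± 0.86. Adjusted over the list alone, 6 were lower. One Ins2+/+ liver on this diet, B 3, had the highest Jun of any liver, at 405 CPM, and 147 CPM of Fos against 6.74 to 8.18 CPM in the other Ins2+/+ livers. Without it the estimate of Fos was −0.92, that of Jun −1.40, that of Gdf15 −1.56 and that of Jund −0.53.

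The remaining lists that passed on diet B were erythroid genes (6 of 6 higher, 3 adjusted over the list alone, camera adjusted p = 8.68e-07), with Hbb-bt, a globin gene with near copies and so an uncertain count, at 1.09 ± 0.38, ribosomal protein genes (34 of 36 higher, 0.000475) and Kupffer markers (13 of 14 higher, 0.00102). Adjusted p was 0.281, 0.92 and 0.854 for them with an estimated correlation. Acinar markers (11 of 11 higher, 7 adjusted over the list alone; 0.00113) rested on few livers, since Cpa1 (5.73 ± 2.22) was higher in 2 of 5. Glycolysis and lipogenesis (19 of 24 lower, 0.00244), extracellular matrix (14 of 20 lower, 1 adjusted over the list alone; 0.0149), with Col3a1 at −0.61 ± 0.17, stellate markers (6 of 7 lower, 0.0187) and targets of the fatty acid receptor PPAR (26 of 37 higher, 0.0187) also passed. Adjusted p was 0.917 for acinar markers and for glycolysis and lipogenesis, and 0.854, 0.281 and 0.963 for the other lists in that order, with an estimated correlation. Of 100 random splits, 39 gave as low a p for Kupffer markers, 35 for PPAR targets, 34 for acinar markers and 30 for glycolysis and lipogenesis. The count was 19 for ribosomal proteins, 16 for immediate early genes and 6 for stellate markers. It was 4 for cholesterol synthesis, for erythroid genes and for matrix. Of the 32 lists, 22 did not pass.

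**Figure D2:**
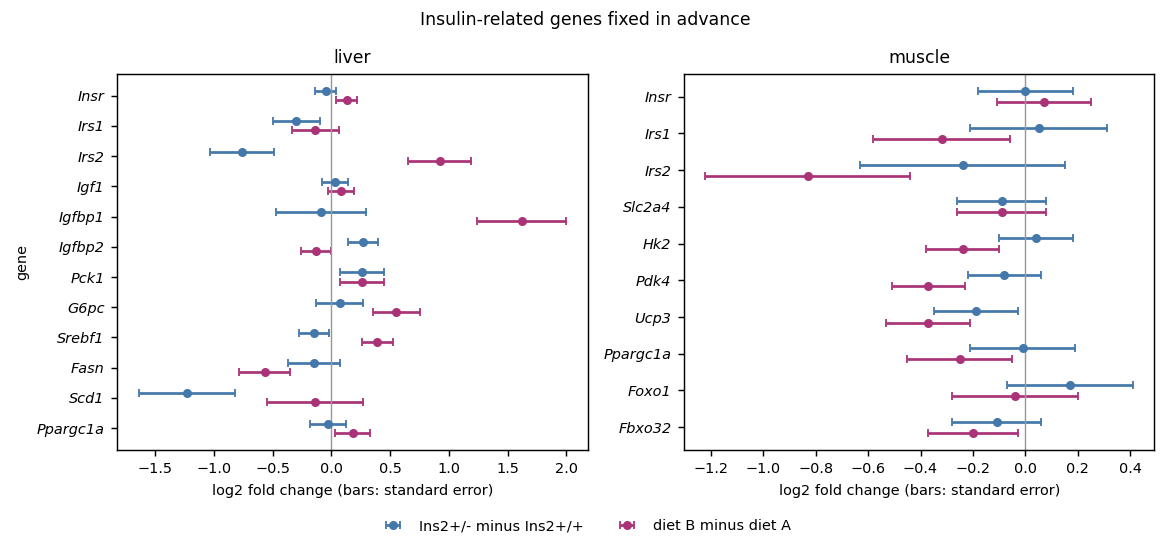
Points are log2 differences with bars of 1 SE for the insulin-action genes fixed beforehand, by gene, for genotype (Ins2+/- minus Ins2+/+) and diet (B minus A) in liver (19 libraries) and muscle (20 libraries). The lowest liver genotype values are those of Scd1 (−1.23) and Irs2 (−0.76), and the highest liver diet value is that of Igfbp1 (1.62). None of the values shown passed the test, and Scd1 is not among the muscle genes shown.

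Diet had the clearest effect on liver. Averaged over genotypes, 28 genes differed between diets, 22 higher and 6 lower on diet B, of 1513 at an unadjusted p under 0.05. With livers Ins2+/- B 2 and B 3 as 1 library the count was 18. Jun, a subunit of the transcription factor AP-1 (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), rose by 2.56 ± 0.41 (5.9-fold, adjusted p = 0.0062), from 19.6 ± 13.3 to 166 ± 165 CPM in Ins2+/+ and from 7.77 ± 1.99 to 34.1 ± 17.8 CPM in Ins2+/- livers. The antiproliferative gene Btg2 rose by 2.12 ± 0.37 (4.36-fold, adjusted p = 0.01). Cyp4a14, a fatty acid omega-hydroxylase and PPAR target with close paralogs (chromosome 4, 115486200 to 115496142), rose by 1.41 ± 0.25 (2.66-fold, adjusted p = 0.0094; 8 of 9 livers), from 194 ± 71.8 to 506 ± 94.6 CPM in Ins2+/+ and from 203 ± 85.1 to 545 ± 239 CPM in Ins2+/- livers. Ccnd1, encoding cyclin D1 of the cell cycle (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925), fell by 0.81 ± 0.11 (0.57-fold, adjusted p = 0.0015), from 78.9 ± 12.3 to 58.6 ± 6.7 CPM and from 110 ± 17 to 48 ± 10.8 CPM.

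The lowest adjusted p belonged to Tns2, which encodes a focal-adhesion protein (ENSMUSG00000037003, chromosome 15, 102100413 to 102116401) and rose by 0.56 ± 0.07 (1.47-fold, adjusted p = 0.00031; 9 of 9 diet B livers above the diet A mean). Grpel2, lower with genotype, was higher on diet B by 0.42 ± 0.06 (adjusted p = 0.0022; 9 of 9). The other genes that rose included Spry4, an inhibitor of receptor tyrosine kinase signalling (0.90 ± 0.14), the MAP kinase phosphatase Dusp1 (1.45 ± 0.29), the phosphatase subunit Ppp1r15a that reverses the stress block on translation (0.85 ± 0.15), and the RNA-binding protein Zfp36l1 (0.95). Further ones were the retinoic acid receptor Rara (0.67 ± 0.11), the glucose transporter Slc2a1 (0.85 ± 0.17), the apolipoprotein Apoa4 (1.00 ± 0.18), the pro-apoptotic Bmf (1.48 ± 0.27), Rnd1 (1.00 ± 0.17), Llgl2 (0.57 ± 0.09), Tmem184a (0.50 ± 0.09), Klf6 (0.72), Erbb3 (0.50), Kank1 (0.47), Pqlc2 (0.44), Arhgap26 (0.42) and Stx2 (0.40). Their adjusted p ranged from 0.0062 to 0.045, and 8 or 9 of the 9 diet B livers showed the direction. Besides Ccnd1, the genes that fell were the cytochrome P450 Cyp2f2 (−1.05 ± 0.18, 0.482-fold, adjusted p = 0.0094), the glutathione transferase Gstm6 (−0.86 ± 0.16), the NKG2D ligand Raet1e (−2.13 ± 0.42), Rbm14 (−0.65 ± 0.13) and the ganglioside activator Gm2a (−0.47 ± 0.08), each in 9 of 9 livers. Cyp2f2, Gstm6, Cyp4a14 and Raet1e belong to families of near-identical genes, so their counts are uncertain.

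**Figure D3:**
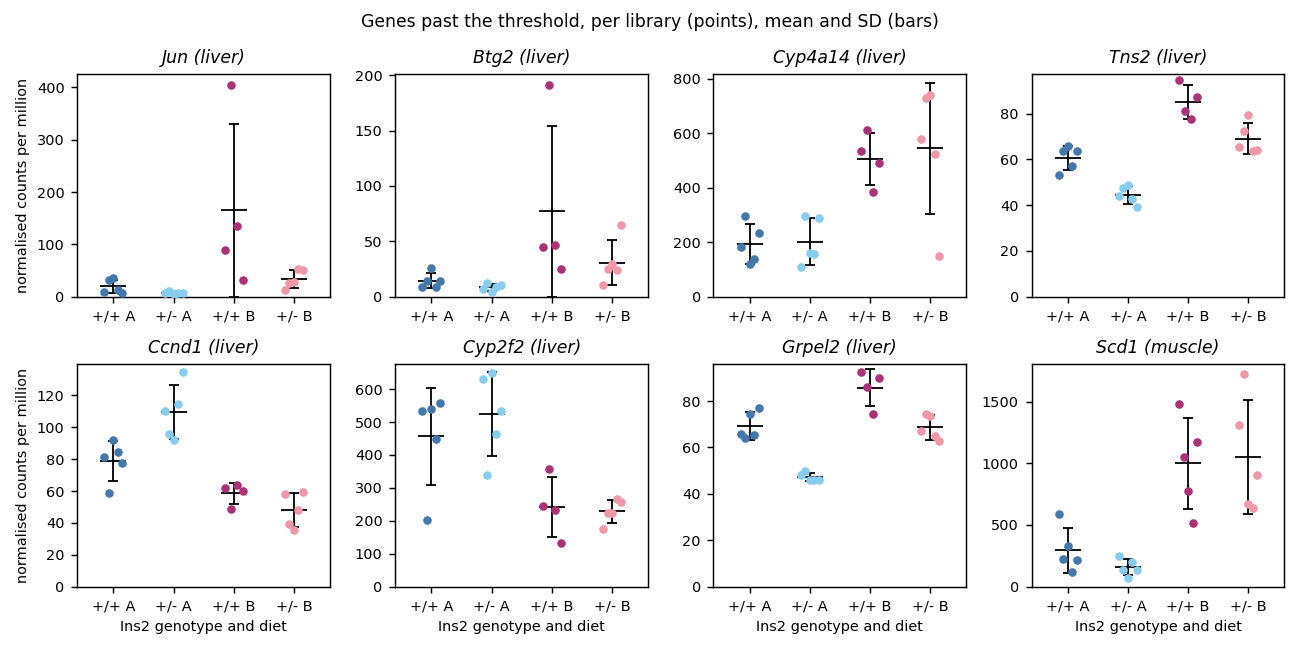
Points are normalised CPM per library for Jun, Btg2, Cyp4a14, Tns2, Ccnd1, Cyp2f2 and Grpel2 in liver and Scd1 in muscle, by genotype and diet, with the mean and SD of each group. Muscle Scd1 stands at 294 and 158 CPM on diet A and at 1000 and 1050 CPM on diet B, and the spread of Jun is widest in Ins2+/+ livers on diet B (166 ± 165 CPM).

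Of the lists, cholesterol synthesis had the lowest camera p for diet. On diet B 22 of its 24 genes were lower (median −0.423, camera adjusted p = 7.98e-15, adjusted p = 0.146 with an estimated correlation), 17 of them when adjusted over the list alone and 0 over all genes. Msmo1 (−0.64 ± 0.14, adjusted p = 0.054), Dhcr7 (−0.50 ± 0.11, 0.053) and the sterol carrier Stard4 (−0.37 ± 0.09, 0.062) led it, each lower in 8 or 9 of 9 livers. Immediate early and heat shock genes were higher for 11 of 16 (median 0.947, camera adjusted p = 8.2e-08, adjusted p = 0.13 with an estimated correlation), with 3 called over all genes (Jun, Btg2 and Dusp1) and 10 adjusted over the list alone. Without liver Ins2+/+ B 3, which had the highest Jun, the estimates of Jun, Btg2 and Dusp1 were 2.09 ± 0.34, 1.63 ± 0.29 and 1.18 ± 0.26, and Dusp1 no longer passed (adjusted p = 0.081), as it did not with the replicate number as a block. Liver Ins2+/- B 1 had the lowest Jun (12.3 CPM) and Btg2 (10.8 CPM) of the diet B livers, and both genes were still called without the livers numbered 1. PPAR targets were higher for 32 of 37 (camera adjusted p = 6.98e-06, adjusted p = 0.313 with an estimated correlation), 5 adjusted over the list alone, with Cyp4a14, Cyp4a31 (0.75 ± 0.19) and the peroxisomal enzyme gene Ehhadh (0.41 ± 0.11).

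Genes of liver detoxification and of sex-biased expression were lower on diet B. Of 30 xenobiotic-metabolism genes 21 were lower (camera adjusted p = 0.00132, adjusted p = 0.254 with an estimated correlation), 8 adjusted over the list alone, with the cytochrome P450 genes Cyp2b10 (−2.09 ± 0.45) and Cyp2c29 (−0.38 ± 0.10). Female-biased genes were lower for 15 of 18 (camera adjusted p = 0.000688; 5 lower and 1 higher adjusted over the list alone), with Cyp3a41a (−0.71 ± 0.18) and Cyp2a4 (−0.50 ± 0.13), and male-biased genes for 9 of 13 (0.00748; 2 lower adjusted over the list alone), with Mup3 (−0.58 ± 0.14). Adjusted p was 0.146 and 0.254 for these with an estimated correlation, and the named members have close paralogs. The growth hormone and IGF1 axis was higher for 14 of 16 (camera adjusted p = 0.00612, adjusted p = 0.13 with an estimated correlation; 2 adjusted over the list alone), with Jak2 (0.41 ± 0.10) and Ghr (0.27 ± 0.09). Insulin-signalling genes were higher for 19 of 30 (camera adjusted p = 0.0238, adjusted p = 0.146 with an estimated correlation; 5 adjusted over the list alone), with Grb10 (0.80 ± 0.19), an inhibitor of the receptor, and Tsc1 (0.41 ± 0.12). Of the fixed genes Igfbp1, a secreted binding protein that insulin represses, was nearest to passing (1.62 ± 0.38, adjusted p = 0.062; 8 of 9), at 39.4 ± 28.4 and 27.7 ± 14.4 CPM on diet A and 86.2 ± 34.4 and 114 ± 68.5 CPM on diet B in Ins2+/+ and Ins2+/- livers. Irs2 (0.92 ± 0.27, adjusted p = 0.12), Srebf1 (0.39 ± 0.13), G6pc (0.55 ± 0.20; 0.38 without liver Ins2+/- B 4), Fasn (−0.57 ± 0.22) and Scd1 (−0.14 ± 0.41) did not pass, nor did Insr (0.13 ± 0.09), Irs1 (−0.14 ± 0.20), Igf1 (0.08 ± 0.11), Igfbp2 (−0.13 ± 0.13), Pck1 (0.26 ± 0.19) and Ppargc1a (0.18 ± 0.15).

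Also lower on diet B were 34 of 36 ribosomal protein genes (camera adjusted p = 5.29e-05), 6 of 6 erythroid genes (3 adjusted over the list alone; 0.000603), 13 of 14 Kupffer markers (0.0132), 20 of 24 genes of glycolysis and lipogenesis (0.0204) and 16 of 22 antioxidant genes (1 adjusted over the list alone; 0.012). In that order, adjusted p was 0.417, 0.254, 0.504, 0.535 and 0.254 with an estimated correlation. Metallothionein Mt1 (−1.22 ± 0.30) and the lipogenic elongase Elovl6 (−0.73 ± 0.26, and −0.50 without liver Ins2+/+ A 3) were examples. Extracellular matrix genes (14 of 20 higher, 0.0068), clock genes (13 of 17 higher, 2 adjusted over the list alone; 0.0171), with Nfil3 at 0.58 ± 0.14, and genes of glucose use in muscle (14 of 21 higher, 1 adjusted over the list alone, Slc2a1; 0.0372) had adjusted p of 0.306, 0.311 and 0.254 with an estimated correlation. Of the 32 lists, 15 did not pass. Of 100 random splits of the livers, the real one included, 32 gave as low a p for Kupffer markers and 29 for glycolysis and lipogenesis. The count was 23 for ribosomal proteins, 21 for matrix, 18 for male-biased genes and 17 for the clock. It was 14 for erythroid and for xenobiotic genes, 13 for PPAR targets, and 11 for antioxidant genes and for glucose use. Lower counts were 6 for female-biased genes and 5 for the growth hormone axis. Cholesterol synthesis, immediate early genes and Ins2 neighbours had 3 each, and insulin signalling 2. By fry 6 lists passed (cholesterol synthesis, immediate early genes, the growth hormone axis, insulin signalling, female-biased genes and Ins2 neighbours, adjusted p from 0.0243 to 0.0437). The number of called genes moved with the method, from 28 by edgeR to 201 by DESeq2 and 292 by limma-voom, and it was 8 without the livers that held islet transcripts. It was 18 with the 2 alike livers as 1 library, and 12 without both.

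Within a genotype, diet called 3 higher and 2 lower genes in Ins2+/- livers (1448 at an unadjusted p under 0.05) and 5 higher genes in Ins2+/+ livers (738). The interaction, which tests whether genotype acts differently on the diets, called 0 of 11777 genes by edgeR (565 at an unadjusted p under 0.05) and 1 by DESeq2. Lowest in p were Zfp874a (0.65 ± 0.15) and Syap1 (0.41 ± 0.11), and on the negative side Rhod (−0.80 ± 0.17), Arrdc2 (−1.03 ± 0.26) and the mRNA-decay gene Zfp36 (−2.22 ± 0.58), each with an adjusted p of 0.98. Zfp36 was at 487 CPM in liver Ins2+/+ B 3 and at 77.7 to 154 CPM in the other Ins2+/+ livers on diet B, and its estimate was −1.33 without B 3. Gemin4, also lowest in p, is given as levels because it had 0 counts in all 4 Ins2+/+ livers on diet B. It averaged 3.66 ± 5.18 and 0.213 ± 0.295 CPM in Ins2+/+ and Ins2+/- livers on diet A, and 4.11 ± 4.01 CPM in Ins2+/- livers on diet B. As groups, the Ins2+/- difference was more negative on diet B for 22 of 24 cholesterol-synthesis genes (median −0.438, camera adjusted p = 6.72e-08), 22 of 24 interferon genes (median −0.430; 1.13e-06), 17 of 20 matrix genes (0.000447) and 12 of 16 immediate early genes (1 adjusted over the list alone; 0.00472). Adjusted p was 0.386 for each of them with an estimated correlation. Examples were Dhcr7 (−0.68 ± 0.22), Isg15 (−0.93 ± 0.37; −0.65 without liver Ins2+/- A 4) and Col3a1 (−0.83 ± 0.25). PPAR targets went the other way (31 of 37 higher, 0.0252, adjusted p = 0.869 with an estimated correlation), but 43 of 100 random splits gave as low a p. The count of such splits was 10 for immediate early genes, 9 for cholesterol synthesis, 8 for interferon genes and 3 for matrix. For Ins2 neighbours (26 of 43 lower; 0.00472, adjusted p = 0.303 with an estimated correlation) the median was −0.061 and the mean 0.013, so that mean and test differed in sign.

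The strain mixed C57BL/6 and 129, and the Ins2 knockout allele was made by targeting, so genes linked to Ins2 can differ between genotypes by strain of origin. On distal chromosome 7, 0 of 89 tested liver genes within 10 Mb of Ins2 were called between genotypes, against 1 of 11688 elsewhere, which is too few calls to compare. At an unadjusted p under 0.01 the shares were 3 of 89 (3.37%) and 292 of 11688 (2.5%; Fisher's exact test, two-sided, p = 0.49). In muscle 0 genes were called near Ins2 or elsewhere, and at an unadjusted p under 0.01 there were 0 of 85 and 43 of 11874 genes (0.362%), so linkage could not be judged there. As a list, 43 neighbours of Ins2 were higher in Ins2+/- livers for 31 genes (median 0.0742, camera adjusted p = 0.00431, adjusted p = 0.24 with an estimated correlation; 0 adjusted over the list alone). On diet A 29 were higher (camera adjusted p = 0.000212, adjusted p = 0.0909 with an estimated correlation). Adjusted over the list alone 5 of them passed, including Lsp1 (1.43 ± 0.40) and the RNA polymerase subunit Polr2l (0.50 ± 0.16), each in 5 of 5 livers. Of 100 random splits of the livers, 1 gave this list as low a p on diet A and 1 for the interaction. This is the lowest count possible, since the real split is included. The count was 3 for genotype averaged over diets and 3 for diet. The list was lower on diet B than on diet A for 27 of 43 genes (camera adjusted p = 0.00947, adjusted p = 0.18 with an estimated correlation; Ccnd1 called over all genes, and 1 higher and 3 lower adjusted over the list alone).

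In muscle no gene passed the test between genotypes. Averaged over diets edgeR called 0 of 11959 genes, with 387 at an unadjusted p under 0.05 where 598 are expected by chance, and DESeq2 and limma-voom also called 0. Lowest in p were Arhgap6 (1.23 ± 0.34, higher in 10 of 10 Ins2+/- muscles), Tmod3 (0.80 ± 0.23) and Srxn1 (0.60 ± 0.18), and A1bg (−2.22 ± 0.51), Trmu (−1.69 ± 0.48) and Txnip (−0.41 ± 0.12), a glucose-induced inhibitor of glucose uptake lower in 10 of 10. Txnip averaged 860 ± 193 and 593 ± 99 CPM in Ins2+/+ and Ins2+/- muscles on diet A and 790 ± 91.1 and 646 ± 96.7 CPM on diet B. The 10 fixed genes had estimates near 0, including the receptor gene Insr (0.00 ± 0.18), the insulin-responsive glucose transporter gene Slc2a4 (−0.09 ± 0.17), hexokinase Hk2 (0.04 ± 0.14), Pdk4 (−0.08 ± 0.14), Irs1 (0.05 ± 0.26), Irs2 (−0.24 ± 0.39), Ucp3 (−0.19 ± 0.16), Ppargc1a (−0.01 ± 0.20), Foxo1 (0.17 ± 0.24) and the atrophy ligase Fbxo32 (−0.11 ± 0.17). Fast-fibre genes were lower for 13 of 14 (median −0.204, camera adjusted p = 0.00374), such as Mybpc2 (−0.26 ± 0.12) and Actn3 (−0.25 ± 0.12), tendon markers for 8 of 8 (0.00296), such as Fmod (−0.54 ± 0.23), and genes of glucose use for 20 of 24 (0.0424). Adjusted p was 0.879, 0.719 and 0.879 for these with an estimated correlation. Muscles Ins2+/- B 2 and B 4 had the lowest Actn3 (3286 and 4064 CPM), against 5290 to 7554 CPM in the other Ins2+/- muscles. The fits without the 4 muscles that stood apart left out these 2, Ins2+/- A 3 and Ins2+/+ B 4. This set was picked after the data were seen and without a fixed rule, so results without it depend on that choice. Without the 4, the fast-fibre and tendon lists still passed and that of glucose use did not, with Fmod at −0.36. Acinar markers were higher for 13 of 13 (0.0487, adjusted p = 0.879 with an estimated correlation), but Reg1 (3.01 ± 1.22) in only 4 of 10 muscles, and the list passed with the opposite sign without those 4 muscles (0.0295). The other 33 of 37 lists did not pass, and no member of the 4 passed when adjusted over the list alone.

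By diet, muscle genotype comparisons called 0 genes by edgeR, with 200 and 543 at an unadjusted p under 0.05 on diets A and B, and 5 and 3 by DESeq2. Ceruloplasmin (Cp), a copper-carrying plasma protein, stood at 35.2 ± 5.25 and 19.9 ± 2.72 CPM in Ins2+/+ and Ins2+/- muscles on diet A and at 20.9 ± 5.04 and 43.6 ± 19.2 CPM on diet B. Its estimates were −0.82 ± 0.25 on diet A and 1.04 ± 0.25 on diet B, each in 5 of 5 muscles (adjusted p = 0.999 and 0.944). On diet A the lowest p values were also those of Degs1 (0.80 ± 0.23), Srxn1 (0.86 ± 0.25), A1bg (−2.89 ± 0.74) and Txnip (−0.53 ± 0.16), and of Mpp2, which had 0 counts in all 5 Ins2+/+ muscles and 2.7 ± 2.31 CPM in Ins2+/- muscles. On diet B they were those of Nupr1 (3.69 ± 0.95), Gatm (2.17 ± 0.57), Ski (−0.76 ± 0.20), Cars2 (−1.35 ± 0.41) and Padi2 (−0.78 ± 0.24). Nupr1 was at 129 and 277 CPM in muscles Ins2+/- B 2 and B 4 and at 6.90 to 7.25 CPM in the other Ins2+/- muscles on diet B. Without the 4 muscles that stood apart the diet B estimates were 0.12 for Nupr1, 1.45 for Gatm, −0.84 for Cars2, −0.38 for Padi2 and 0.47 for Cp. The fixed genes ranged from −0.74 ± 0.55 (Irs2, −0.12 without muscle Ins2+/+ A 5) to 0.34 ± 0.34 (Foxo1) on diet A and from −0.26 ± 0.23 (Ucp3) to 0.27 ± 0.56 (Irs2) on diet B, and none passed. Hepatocyte markers, which include plasma-protein genes, were lower in Ins2+/- muscles for 10 of 10 on diet A (median −0.888, camera adjusted p = 2.98e-05, adjusted p = 0.59 with an estimated correlation) and higher for 9 of 10 on diet B (median 1.23; 0.000495, adjusted p = 0.522 with an estimated correlation). On diet A xenobiotic genes (15 of 18 lower, 0.00923), female-biased liver genes (7 of 10 lower, 1 adjusted over the list alone; 0.00928), tendon markers (8 of 8 lower, 0.00923) and matrix genes (18 of 22 higher, 0.0149) also passed. Adjusted p was 0.59, 0.516, 0.516 and 0.83 for them with an estimated correlation. Whether the liver transcripts came from liver RNA in these libraries was not tested.

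On diet B lower lists in Ins2+/- muscles were fast-fibre genes (13 of 14, camera adjusted p = 0.000495), with Eno3 (−0.49 ± 0.18) and Aldoa (−0.41 ± 0.15) of glycolysis. Genes of glucose use (20 of 24, 0.000495), matrix genes (21 of 22, 0.00428), macrophage markers (7 of 9, 0.0192) and myofibre genes (8 of 10, 0.0229) were lower too. The macrophage list is the one called Kupffer markers in liver. Higher were xenobiotic genes (13 of 18, 0.0192), cholangiocyte markers (5 of 5, 1 adjusted over the list alone; 0.0403), acinar markers (13 of 13, 12 adjusted over the list alone; 0.00629), genes of the unfolded protein response (22 of 27, 0.00584), with Hspa5 at 0.71 ± 0.29 (0.17 without muscle Ins2+/- B 4), and interferon genes (15 of 17, 0.0403). Adjusted p was 0.624 for acinar markers and 0.522 for each of the others with an estimated correlation. Muscle Ins2+/- B 4 held the most acinar transcripts (37800 CPM) and the most albumin (1480 CPM) of any muscle, and acinar, cholangiocyte, interferon and unfolded-protein lists turned negative without it and the 3 other muscles that stood apart. Eno3 was at 1884 and 2350 CPM in muscles Ins2+/- B 2 and B 4 and at 3974 to 4035 CPM in the other Ins2+/- muscles on diet B. Without the 4 muscles the fast-fibre and macrophage lists still passed, and the hepatocyte, glucose-use, matrix, myofibre and xenobiotic lists did not. On diets A and B 32 and 26 of the 37 lists did not pass.

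Scd1 was the only muscle gene that edgeR called for diet averaged over genotypes, where 54.3% of simulated 2-fold changes were recovered. This desaturase gene (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879, minus strand) rose on diet B by 2.24 ± 0.28 (4.74-fold, adjusted p = 0.00031), from 294 ± 182 to 1000 ± 369 CPM in Ins2+/+ and from 158 ± 68.8 to 1050 ± 464 CPM in Ins2+/- muscles, and in 10 of 10 diet B muscles. It was called in Ins2+/- muscles by themselves (1 gene; 577 at an unadjusted p under 0.05), while 0 genes were called in Ins2+/+ muscles (299), and its interaction of 0.96 ± 0.53 did not pass (adjusted p = 1). Adipocyte markers were higher on the same diet for 9 of 10 (median 0.389, camera adjusted p = 0.00699, adjusted p = 0.877 with an estimated correlation), with Retn, the adipokine resistin, at 1.25 ± 0.56 (9 of 10 muscles) and Adipoq at 0.63 ± 0.37. Islet (9 of 9, 0.0307) and acinar markers (13 of 13, all 13 adjusted over the list alone; 4.63e-05) were higher too, with Amy2a5, pancreatic amylase, at 7.16 ± 1.72 in 5 of 10 muscles. Mitochondrially encoded genes were higher for 13 of 13 (0.00154), with mt-Co1 at 0.36 ± 0.17, but muscle Ins2+/- B 2 held 123300 CPM of mt-Co1, against 32400 to 56830 CPM in all others. Without that library the list did not pass, without the 4 muscles that stood apart it did, and 42 of 100 random splits gave it as low a p. Genes of muscle growth and atrophy (15 of 20, 0.0249), fast-fibre genes (13 of 14, 0.0307) and genes of glucose use (17 of 24, 0.0307) were lower, among them the ubiquitin ligase Trim63 (−0.60 ± 0.20), myostatin (Mstn, −0.53 ± 0.20) and Mylpf (−0.27 ± 0.11). Adjusted p was 0.877 for each of these 6 lists with an estimated correlation, and 30 of 37 lists did not pass. Without the 4 muscles the adipocyte list still passed, and the islet, acinar, growth and atrophy, fast-fibre and glucose-use lists did not. Retn was then at 0.73, Amy2a5 at 3.15, Trim63 at −0.38 and Mstn at −0.27. Adipoq was at 0.44 without muscle Ins2+/- B 2. Whether the Scd1 rise and the higher adipocyte markers share a source was not tested.

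The lowest diet estimates among the 10 fixed muscle genes were those of Irs2, Pdk4, which switches off pyruvate oxidation, and Ucp3. They stood at −0.83 ± 0.39 (−0.53 without muscle Ins2+/+ A 5), −0.37 ± 0.14 and −0.37 ± 0.16, each lower in 9 of 10 muscles (adjusted p = 1). Hk2 (−0.24 ± 0.14), Irs1 (−0.32 ± 0.26), Slc2a4 (−0.09 ± 0.17), Insr (0.07 ± 0.18), Ppargc1a (−0.25 ± 0.20), Foxo1 (−0.04 ± 0.24) and Fbxo32 (−0.20 ± 0.17) did not pass either. edgeR counted 454 genes at an unadjusted p under 0.05 for diet, and DESeq2 called 6. The Scd1 call was lost without the 9 muscles that held islet transcripts, at 2.14 (adjusted p = 0.081).

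The interaction in muscle called 0 genes by edgeR (387 at an unadjusted p under 0.05) and 0 by DESeq2. Cp had the lowest p (1.86 ± 0.36, adjusted p = 0.31), followed on the positive side by Arid4b (1.30 ± 0.38) and Smc6 (1.28 ± 0.39) and on the negative side by Kif24 (−4.91 ± 1.36), Ccl6 (−1.95 ± 0.56) and Mpp2, given above as levels. All 10 hepatocyte markers had a positive interaction (median 2.16, camera adjusted p = 1.24e-08; 7 adjusted over the list alone), with the iron carrier gene Trf at 1.47 ± 0.51 and the urea-cycle gene Cps1 at 2.66 ± 0.94, as did 16 of 18 xenobiotic genes (0.000167) and 8 of 10 female-biased liver genes (0.0186). Adjusted p was 0.354 for each with an estimated correlation, and liver RNA in these libraries was not tested as a source. Matrix genes were negative (19 of 22, 9.3e-05), as were macrophage markers (8 of 9, 0.00994), genes of glucose use (17 of 24, 0.00797) and fast-fibre genes (12 of 14, 0.0354). Acinar markers (13 of 13, 0.00994) and unfolded-protein genes (22 of 27, 0.0234) were positive. Adjusted p was 0.399 and 0.354 for the first pair and 0.669 for the other lists with an estimated correlation. Without the 4 muscles that stood apart the acinar (0.0685) and unfolded-protein (0.855) lists changed sign, and the fast-fibre and glucose-use lists did not pass. The estimates were then 1.30 for Cp, 0.84 for Arid4b, 0.95 for Trf and 1.64 for Cps1.

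Liver and muscle were also compared directly over 10517 genes. The genotype effect differed for 0 genes by edgeR (426 at an unadjusted p under 0.05) and 14 by DESeq2. Lowest in p were Eif2b4 (0.71 ± 0.18), Rrp12 (0.89 ± 0.25) and Trmu (1.67 ± 0.46) on the positive side, and Ggnbp2 (−0.63 ± 0.16), Arhgap6 (−1.23 ± 0.33) and Agfg2 (−1.30 ± 0.36) on the negative side (adjusted p = 1). Cholesterol synthesis was lower in liver relative to muscle for 18 of 23 genes (camera adjusted p = 0.00875). Kupffer and macrophage markers (9 of 9, 0.0136) and ribosomal protein genes (25 of 36, 0.0209) were higher. Adjusted p was 0.543, 0.543 and 0.969 with an estimated correlation. The diet effect differed for 0 genes by edgeR (523) and 16 by DESeq2, with Jun nearest to passing (2.84 ± 0.55, adjusted p = 0.086), then Atf3 (3.86 ± 0.91), Ppp1r15a (1.36 ± 0.32) and Scd1 (−2.36 ± 0.54) at 0.32, and Idi1 (−1.26 ± 0.33) and Fgd5 (−1.18 ± 0.31) at 0.41. The Scd1 rise with diet in muscle was thus not shown to differ from its liver estimate. As groups, cholesterol synthesis was lower with diet B in liver relative to muscle for 21 of 23 genes (median −0.419, camera adjusted p = 7.63e-07, adjusted p = 0.128 with an estimated correlation; 2 adjusted over the list alone) and immediate early genes were higher for 14 of 16 (median 0.925; 3.61e-06, adjusted p = 0.287 with an estimated correlation; 3 adjusted over the list alone). The liver minus muscle diet difference was also positive for genes of glucose use in muscle (18 of 21, 2 adjusted over the list alone; 0.00289), of matrix (18 of 20, 0.0108), of the clock (15 of 17, 1 adjusted over the list alone; 0.0206) and of muscle growth and atrophy (9 of 11, 1 adjusted over the list alone; 0.0402), with adjusted p of 0.313, 0.47, 0.313 and 0.287 with an estimated correlation. It was negative for acinar markers (11 of 11, 2 adjusted over the list alone; 0.00179), glycolysis and lipogenesis (18 of 24, 1 adjusted over the list alone; 0.0108), erythroid genes (5 of 6, 0.0185), mitochondrially encoded genes (13 of 13, 0.0204, with muscle Ins2+/- B 2 included) and myofibre genes (6 of 6, 0.0206). For these adjusted p was 0.53, 0.313, 0.313, 0.72 and 0.47 with an estimated correlation, and 29 and 21 of the 32 lists did not pass for genotype and diet.

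Across genes with a mean log2 CPM above 3, genotype effects on the diets had a correlation of 0.422 in liver (Pearson; Spearman 0.196; 8487 genes) and 0.23 in muscle (Spearman 0.00446; 8243 genes), computed from separate libraries. Diet effects in the 2 genotypes correlated at 0.365 in liver (Spearman 0.277) and 0.384 in muscle (Spearman 0.0448). Between tissues the correlations were 0.288 for genotype (Spearman 0.0489) and 0.104 for diet (Spearman 0.0393; 6714 genes). The share of genes with the same sign was 58.9% for liver diet effects, 56.6% for liver genotype effects, and 49.9% to 51.4% for the 4 other pairs. Genes are not independent replicates, so no p is given for these relations.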

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

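The tests of islet transcripts were chosen only after those transcripts had been seen; the regroupings of the libraries, except those with 2 livers as 1, and the tests of immediate early genes were fixed before their results were seen. Chance flags about 1 in 20 groups, and of 224 groups of libraries 21 held a library far from the others where 11 are expected, each given with its gap to the nearest library as a share of the group's range.

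Ins2 made up 6 of the 21. The distant liver libraries were Ins2+/- B 1 (2070 against 26.2 CPM, share 0.987), Ins2+/+ A 1 (18.8 against 1.66, 0.921) and Ins2+/+ B 2 (76.4 against 0.792, 0.993). The muscles were Ins2+/- A 2 (4100 against 7.54, 0.999), Ins2+/+ A 3 (1320 against 22.2, 0.984) and Ins2+/+ B 3 (2200 against 481, 0.782).

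Ins2 and the other islet hormones rose together in 15 libraries of both tissues. RNA from islets of mice with an intact Ins1 gene is argued against, since Ins1 had 0.024 counts per 1000 counts of Ins2 in them; muscle Ins2+/- B 5, outside these 15, held 11 counts of Ins1. Pancreas carried along at dissection stays open, because 11 of the 15 had an acinar marker sum below Ins2, while the highest sum, 37800 CPM, came with 12900 CPM of Ins2. Ins2 and the acinar sum also rose together, with r = 0.905 in the 9 muscles (exact permutation p = 0.00039) and 0.774 in the 6 livers (p = 0.053). The genotype or diet of the animal stays open as well, with a lowest Fisher's exact p of 0.628 in 4 comparisons at these numbers of libraries. A candidate explanation is islet-rich pancreatic RNA that reached a library at dissection or later, and which step it was has not been tested.

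Immediate early genes were called higher in livers on diet B (Jun, Btg2 and Dusp1), and Btg2 in liver Ins2+/+ B 3 lay far above its group (191 against 46.5 CPM, share 0.871). Islet carry-over is argued against as the cause, since the median of the 3 estimates was 2.37 without the libraries holding islet transcripts, against 2.12 with all. Of the 3 only Jun still passed there (adjusted p = 0.049; 0.07 for Btg2 and for Dusp1), in a fit of fewer livers. A single liver with very high levels stays open in part, as 2 of the 3 genes still passed without it. Handling before freezing was not tested, and diet itself stays an open biological explanation.

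Regrouping the libraries at random, 100 splits with the real one included, tested whether chance could give as many calls. For liver diet only the real split reached its 28 genes (highest other 16) and its 17 lists (highest other 16, a narrow margin). For muscle diet only the real split reached its 1 gene (highest other 0). Such counts were thus rare among the splits. Chance is not excluded, since 1 in 100 is the lowest share that 100 splits can show and many comparisons were tested. With livers Ins2+/- B 2 and B 3 as 1 library, 2 splits reached the real 18 genes (highest other 26) and 2 the real 17 lists (highest other 17). For single liver diet lists chance stays open where many splits gave as low a p, such as 32 for Kupffer markers, 29 for glycolysis and lipogenesis, 23 for ribosomal proteins, 21 for matrix and 18 for male-biased genes. It also stays open for the clock (17), erythroid and xenobiotic genes (14 each), PPAR targets (13), and antioxidant genes and glucose use (11 each). Some muscle genotype lists had such counts too, as with 51 for acinar markers averaged over diets and 24 for hepatocyte markers on diet A. Other muscle lists had low counts, such as 2 for tendon markers averaged over diets. On diet B the count was 1 for matrix, 4 for fast-fibre genes and 5 for macrophage markers, and in the interaction 1 for macrophage markers. With 37 lists tested per comparison, chance is not excluded for these either. For the other numbers of called genes or lists 6 or more splits reached the real one. For liver genotype averaged over diets 7 splits gave the real 1 gene or more (highest other 16) and 16 the real 11 lists (19), on diet A 11 gave 1 gene (4) and 16 gave 10 lists (15), and on diet B 39 gave 10 lists (18). For the liver interaction 77 gave 6 lists (18). For muscle, 83 splits gave the 4 lists of genotype (17), 69 the 5 on diet A (12), 23 the 11 on diet B (17), 50 the 7 of diet (13) and 29 the 9 of the interaction (15). Between tissues 76 gave the 3 lists of genotype (11) and 6 the 11 of diet (13).

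In the comparisons with 0 called genes all 100 splits reached that count. The highest other counts were 2 for liver genotype on diet B, 11 for the liver interaction, 101, 2 and 58 for muscle genotype averaged, on diet A and on diet B, 83 for the muscle interaction, and 35 for each comparison between tissues. Some splits thus called up to 101 muscle genes where the real one called 0. What sets the muscle libraries apart in those splits was not tested.

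The other distant libraries are given as values. In liver they were Fasn in Ins2+/- B 4 (985 against 487 CPM, share 0.745), Gstm6 in Ins2+/- B 5 (41.7 against 21.8, 0.821) and Ins2+/+ A 2 (26.2 against 50.6, 0.816), and Raet1e in Ins2+/- B 5 (12.4 against 3.23, 0.808) and Ins2+/+ B 5 (2.16 against 3.65, 0.867). Arhgap26 in Ins2+/- B 1 (26.3 against 33.5, 0.727), Klf6 in Ins2+/- A 3 (18.5 against 12.1, 0.765), Stx2 in Ins2+/- A 1 (16.4 against 12, 0.788) and Scd1 in Ins2+/+ A 3 (21000 against 6870, 0.749) followed. In muscle, Pdk4 was lowest in Ins2+/+ B 1 (838 against 1280, 0.721) and Ins2+/+ A 1 (1120 against 1770, 0.831). Muscle Ins2+/- A 3, the shallowest library, stood apart for Slc2a4 (278 against 374, 0.74), Ucp3 (121 against 214, 0.831) and Fbxo32 (429 against 307, 0.722).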

How the results depend on the processing

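Fits with robust estimation, without or adjusted for islet transcripts, without the 4 muscles that stood apart, without the number 1 livers, without the 2 deepest livers and with these 2 as 1 library were chosen after seeing the data. Unless a cause is given, the cause was not tested. Fits that leave out libraries hold fewer samples by construction.

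The diet comparisons within a genotype were not run under the alternatives. Of the 31 called genes of the other comparisons, counted per comparison, none changed direction under any alternative run. In every fit that left out a library 19 passed, and 5 (Tns2, Spry4, Jun, Ccnd1 and Ppp1r15a, all for liver diet) passed in every setting. Grpel2 for liver genotype kept a log2 ratio of −0.47 to −0.39, with adjusted p from 1.6e-06 to 0.12. On diet A it ranged from −0.60 to −0.51, with adjusted p from 0.00057 to 0.25. Muscle Scd1 for diet ranged from 2.11 to 2.45. Of 104 list calls, 57 passed in every fit that left out a library and 0 with an estimated correlation.

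For liver genotype averaged over diets the count of 1 became 32 by DESeq2, 14 by limma-voom, 4 with robust estimation, 4 at an adjusted p below 0.1, 3 with the stricter filter, 2 with a surrogate variable, 2 without the 2 deepest livers, 4 without the number 1 livers and 0 without the livers holding islet transcripts. Leaving out single livers gave 1 to 8 calls: 8 without Ins2+/+ A 1, 4 without Ins2+/- A 1, and 2 each without Ins2+/+ B 4 and Ins2+/- A 3, B 3 and B 5. On diet A the count of 1 became 14 by DESeq2, 7 at an adjusted p below 0.1, 5 with robust estimation, 10 without the number 1 livers, and 0 by limma-voom, with no filter (more genes tested), in the 2 groups alone, without the islet libraries or without the 2 deepest livers. Single livers gave 0 to 8: 8 without Ins2+/+ A 1, 3 without Ins2+/+ A 5, 2 without Ins2+/+ B 2, and 0 without Ins2+/- A 1 to A 5, Ins2+/- B 1 or Ins2+/+ A 3, A 4 and B 5. On diet B the count of 0 became 37 by limma-voom and 1 with a surrogate variable; single livers gave 0 to 1 (1 without Ins2+/+ B 5).

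For liver diet the count of 28 became 201 by DESeq2, 292 by limma-voom, 170 at an adjusted p below 0.1, 86 with a surrogate variable, 83 with the islet level as a covariate, 78 without the number 1 livers, 18 with the 2 deepest livers as 1 library, 12 without the 2 deepest livers and 8 without the islet libraries. All 28 genes were among the calls of DESeq2, limma-voom, the surrogate and the covariate fit, and 25, 18, 11 and 6 in the last 4 fits named. With the 2 livers as 1, which are more alike than any other pair, Gstm6, Raet1e, Rbm14, Slc2a1, Klf6, Erbb3, Zfp36l1, Pqlc2, Stx2 and Arhgap26 did not pass, and no other count changed. Single livers gave 17 to 110: 110 without Ins2+/- B 5, 103 without Ins2+/+ A 2, 89 without Ins2+/- B 1, 57 without Ins2+/- A 1, 17 without Ins2+/- B 4, and 18 each without Ins2+/- B 2, B 3 and Ins2+/+ B 2. The liver interaction gave 1 by DESeq2.

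In muscle DESeq2 gave 5 and 3 calls for genotype on diets A and B and 6 for diet, where edgeR gave 0, 0 and 1. The diet count was also 2 with no filter, 8 with the islet covariate and 0 without the islet libraries; leaving out single muscles changed no count. Between tissues DESeq2 gave 14 for genotype and 16 for diet, and diet gave 1 at an adjusted p below 0.1. Single libraries gave 0 to 1 for genotype (1 without muscle Ins2+/+ B 1) and 0 to 2 for diet: 2 without muscle Ins2+/- A 1, and 1 each without liver Ins2+/- B 1, Ins2+/+ A 3, Ins2+/+ B 5 or muscle Ins2+/+ A 1. The stricter filter removed no gene tested between tissues, so it says nothing there.

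Lists that changed sign did so in muscle. Without the 4 muscles that stood apart these were, with camera adjusted p, hepatocyte (0.0295), mitochondrially encoded (0.000418) and acinar (0.0295) for genotype, cholangiocyte (0.18), PPAR (0.0206), interferon (0.474), acinar (0.00852), islet (0.00852) and unfolded protein (0.614) for genotype on diet B, islet (0.818) for diet, and PPAR (0.0111), acinar (0.0685), islet (0.0307) and unfolded protein (0.855) for the interaction. Without the islet libraries interferon (0.974) and unfolded protein (0.974) turned on diet B. Without muscle Ins2+/- B 2, the library richest in mitochondrial counts, the mitochondrial list turned on diet B (0.0115); leaving out single muscles gave 0.000323 to 0.347 for the list mitochondrially encoded in muscle genotype on diet B.

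Pairs of the same replicate number correlated above 0.1 more often than pairs of different numbers. The counts were 8 of 27 against 17 of 108 in liver, and 8 of 30 against 6 of 120 in muscle. Between tissues they were 1 of 19 against 1 of 76, and 7 of 19 livers correlated best with their own number. Whether the numbers mark a pairing or a shared batch is not known. The number 1 libraries were part of this, with a correlation of 0.271 on average in liver (3 pairs) and 0.231 in muscle (6 pairs). All of these number 1 pairs were above 0.1, and Ins2+/+ livers on diet B have no number 1. With the number as a block, liver genotype gave 1 call, genotype on diet A 0, and diet 42 (24 shared with the 28; Dusp1, Zfp36l1, Raet1e and Pqlc2 did not pass). Depth limits weakly expressed genes, since 3 counts equal 2.83 CPM in the shallowest muscle.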

Other observations

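Muscles differed in genes that respond to activity or handling within minutes, given here as CPM of the library total. Fos, a partner of Jun in AP-1, ranged from 2.41 to 5.98 CPM in the muscles numbered 1 (median 3.16) and from 2 to 620 CPM in the others (median 160). Egr1, another immediate early gene, ranged from 2.22 to 5.81 CPM in the muscles numbered 1 and from 15.5 to 276 CPM in the others. The numbers name libraries within groups, and no group difference is drawn from these values. Of the livers numbered 1, those on diet A lay within the range of their diet for Jun and Btg2, and Ins2+/- B 1 was the lowest on diet B.

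Some transcripts of each tissue were read in the other. Albumin (Alb) stood at 74800 to 119000 CPM in livers and 75.3 to 1480 CPM in muscles, and skeletal actin (Acta1) at 0 to 29.8 CPM in livers. Other liver transcripts also varied widely between muscles, with Apoa1 at 3.08 to 119 CPM and Ttr at 7.45 to 269 CPM. All 3 were highest in muscle Ins2+/- B 4. In normalised CPM, liver transcripts were highest in the same muscles, Ins2+/+ A 2, A 3 and A 5 and Ins2+/- A 5 and B 4. Apoa1 was at 33.0 to 113.4 CPM there and at 2.7 to 22.1 CPM in the other muscles. Apoa2 was at 41.5 to 109.2 against 5.4 to 34.4 CPM, and Cyp2a5 at 11.4 to 40.6 against 0 to 8.9 CPM. Liver RNA in muscle libraries was not tested as a source of the hepatocyte, xenobiotic and female-biased list results in muscle. Those results are therefore not shown to be changes within muscle itself. The first principal components of muscle took 19.5% and 16.5% of the variance, and those of liver 13.9% and 11.5%.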
